A study of Mus musculus with 10 samples.

How the data were processed

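RNA was measured in 10 libraries of innate lymphoid cells sorted from the skin of adult B6 mice. Total RNA was isolated on columns and made into libraries with a low-input full-length cDNA kit (SMART-Seq) and Nextera XT, per the labels' protocols, a preparation that does not mark the strand of origin. Per the submitters' processing notes, Trimmomatic, STAR and RSEM were used with the mm10 genome build. Their versions, order and settings, the strand setting of the counting and the annotation release are not given in the sources used here. Each library has 1 deposited table of gene results from RSEM, per the file headers. The expected counts in it are the deposited estimates of reads or fragments per gene, in which RSEM splits ambiguous reads between genes. Between 7.2% and 8.39% of the values were not whole. The TPM values are deposited too and are, per the file headers, RSEM's transcript abundances, corrected for effective gene length and scaled to a common total. FPKM values, also computed by RSEM before deposit per the file headers, were not used here. Without strand, reads of a gene and of an antisense or overlapping partner cannot be separated. Reads of near-identical genes, such as keratins, Ly6 family members, Gimap genes, Apol9 genes, late cornified envelope genes and haemoglobin genes, may be split with error.

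Samples were grouped by layer and by the sort marker in their titles, into epidermal (3 libraries), dermal CCR6+ (2), dermal Sca1+ (2) and subcutaneous (3). The cell type label of the second dermal library of either sort names no marker, so the title was used, and the series design speaks of triplicates, while 2 libraries were analysed here for either dermal population. Gene IDs with version were matched to GENCODE M21 (GRCm38, the assembly of mm10). Of 47643 IDs in each file, 47224 carried a symbol and were placed by it, 39106 of them in the same version, and 419 had no symbol. Coordinates are those of GENCODE M21.

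Expected counts were rounded to whole numbers. The groups, the gene lists, the tests and all alternatives except 1 were chosen before the data were examined. Genes were kept by edgeR's filterByExpr by group with a count minimum of 10, which left 16208. With TMM normalization, 1 model with the 4 groups as terms was fitted to all 10 libraries by edgeR's quasi-likelihood method (glmQLFit and glmQLFTest, two-sided), so that all groups shared 1 estimate of the spread. The biological coefficient of variation was 0.62. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. The SE given with an edgeR log2 fold change is its absolute value over the square root of the F statistic. It was derived in this way and is not an output of the model. The main comparisons were epidermal with subcutaneous, epidermal with dermal CCR6+, dermal CCR6+ with dermal Sca1+, and dermal Sca1+ with subcutaneous ILCs. The secondary ones were epidermal with dermal Sca1+ and dermal CCR6+ with subcutaneous ILCs. Genes highest in a group had to be called and higher in it in all 3 comparisons with the other groups.

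A total of 26 gene lists was tested in the 6 comparisons by limma's camera on edgeR log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 156 pairs. A list needed at least 3 measured members. Its genes were also counted with p-values adjusted over the list alone. Principal components were computed from the same log2 CPM values, and CPM levels use TMM library sizes.

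Genes were named by a rule. Per main comparison and direction, it took the called genes with all libraries of the higher group above all of the lower group and a mean of at least 20 CPM in the higher group. Of these it named the 8 with the largest fold change among genes with more than 3 counts over the lower group, and the 3 with the highest mean among the rest. In the secondary comparisons it named 4 and 2. For each group it named the 8 genes highest in it by the smallest fold change over the 3 comparisons. Predicted genes, mitochondrially encoded genes, ribosomal protein genes and antigen receptor segments were left out of these ranks. Ccr6, Ly6a, Ptprc, Thy1 and Il7r and example members of the lists were also named, the examples after their values were seen. The result of 1 gene is not reported here.

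Where the lower group had no count, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio has a 95% exact Poisson interval. Library totals lay between 11627222 and 18118544.

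The alternatives were RLE size factors, DESeq2 with its own size factors, limma-trend on log2(TPM + 1), no filter beyond 1 count, a filter of 5 CPM in 2 libraries, robust dispersions, an offset for effective gene length, an absolute log2 fold change of at least 1, only the 2 groups compared in the fit, a replicate block by title number or by runs of the numbers in the deposited names, an estimated inter-gene correlation or fry for the lists, and leaving out each library in turn. Leaving out epidermal replicate 1 and subcutaneous replicate 1 together was added after seeing the data.

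The test was tried on simulated counts with 200 changed genes per comparison. Of genes changed by a fold of 4, it called 49% between epidermal and subcutaneous groups (15534 genes tested), 50% between epidermal and dermal CCR6+ (15499), 32% between dermal CCR6+ and dermal Sca1+ (15506), 42% between dermal Sca1+ and subcutaneous (15517), 35% between epidermal and dermal Sca1+ (15513) and 34% between dermal CCR6+ and subcutaneous groups (15496). Of genes changed by a fold of 2 it called 3%, 2%, 0%, 4%, 2% and 2% in the same order, and 8.8%, 3.7%, 0%, 6.1%, 0% and 0% of the calls were unchanged genes. Camera called the simulated changed list in 3 of 3 comparisons and none of 120 pairs of an unchanged list and a comparison. Simulated genes varied independently of each other, and changed genes were not drawn from those with the lowest levels. These counts therefore do not show how often camera calls an unchanged list of correlated genes. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.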

Results

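Innate lymphoid cells (ILCs), tissue lymphocytes that lack rearranged antigen receptors, were sorted from the skin of adult B6 mice and their RNA was sequenced in 10 libraries. Of these, 3 held ILCs of the epidermis, the outer epithelial layer, 2 held dermal ILCs sorted as CCR6+, 2 held dermal ILCs sorted as Sca1+, and 3 held ILCs of the subcutaneous layer. CCR6 is a chemokine receptor, and Sca1 is a surface protein encoded by Ly6a. The total of the deposited expected counts ranged from 11627222 to 18118544 per library, and between 15013 and 19435 genes had at least 1 count. Levels are given as CPM, counts scaled to a common library size, in which 3 counts of a library corresponded to between 0.166 and 0.258. Mitochondrial transcripts took between 1.61% and 4.9% of the counts. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 42.8 for each pair, so every library was counted once. The labels do not say whether replicates came from separate animals, and p-values therefore reflect the spread between these libraries, which may be technical. CPM values are normalized and given as mean ± SD over the libraries of a group, and intervals and floors cover counting error only.

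The libraries separated by group along the first principal component of log2 CPM, which held 44.2% of the variance. Epidermal libraries had scores of -163.5 to -133, dermal CCR6+ libraries -51.7 and 1.7, dermal Sca1+ libraries 39 and 47.7, and subcutaneous libraries 133.8 to 139. Spearman correlations across genes, which are not independent replicates, were 0.941 to 0.955 between epidermal libraries and 0.755 to 0.806 between epidermal and subcutaneous libraries. Dermal CCR6+ libraries had correlations of 0.864 to 0.908 with the epidermal and of 0.899 to 0.926 with the dermal Sca1+ libraries. Dermal Sca1+ libraries had correlations of 0.874 to 0.892 with the subcutaneous libraries.

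**Figure D1:**
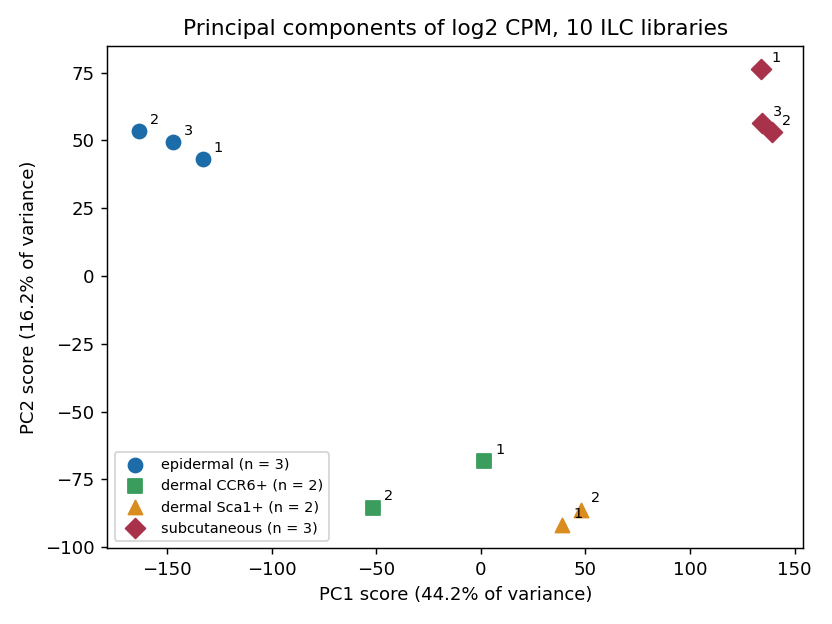
Scores of the 10 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with replicate numbers beside the points. The first component holds 44.2% and the second 16.2% of the variance, and the 3 epidermal and 3 subcutaneous libraries lie at opposite ends of the first.

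The genes of both sort markers were examined first. Ccr6 (ENSMUSG00000040899.13, chromosome 17, 8236043 to 8257141, mm10) was at 1128 ± 200 CPM in epidermal ILCs (SD, n = 3), 833 ± 76.9 in dermal CCR6+ ILCs (n = 2), 71.3 ± 42.9 in dermal Sca1+ ILCs (n = 2) and 8.10 ± 13.9 in subcutaneous ILCs (n = 3). Ly6a (ENSMUSG00000075602.10, chromosome 15, 74994877 to 74998031, mm10), which has close paralogs in its gene family that can share reads, was at 207 ± 51.5, 157 ± 78.9, 1406 ± 17.3 and 1520 ± 331 CPM in the same order. Within the dermis, Ly6a was lower in CCR6+ than in Sca1+ ILCs with a log2 fold change of -3.16 ± 0.388 (SE) and an adjusted p of 0.00512 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the test behind each edgeR adjusted p given here. Both CCR6+ libraries exceeded both Sca1+ libraries in Ccr6, but that difference missed the threshold (log2 fold change 3.55 ± 1.54, edgeR adjusted p = 0.442). The pan-leukocyte gene Ptprc and the IL-7 receptor gene Il7r were not called in any of the 6 comparisons. Thy1, a surface marker of many ILCs, was higher in epidermal than in subcutaneous ILCs (193 ± 55.0 against 85.6 ± 21.4 CPM, edgeR adjusted p = 0.00906). It was also higher in dermal CCR6+ than in subcutaneous ILCs (231 ± 0.250 CPM, edgeR adjusted p = 0.0122), a call that was lost without dermal CCR6+ replicate 2, as was that of Ccr6 in the same comparison (edgeR adjusted p = 0.0229 with all libraries and between 0.0736 and 0.0759 for both genes without it). The Ccr6 call was also lost in a fit of these 2 groups alone (edgeR adjusted p = 0.061), as was that of Ly6a within the dermis (0.0507).

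**Figure D2:**
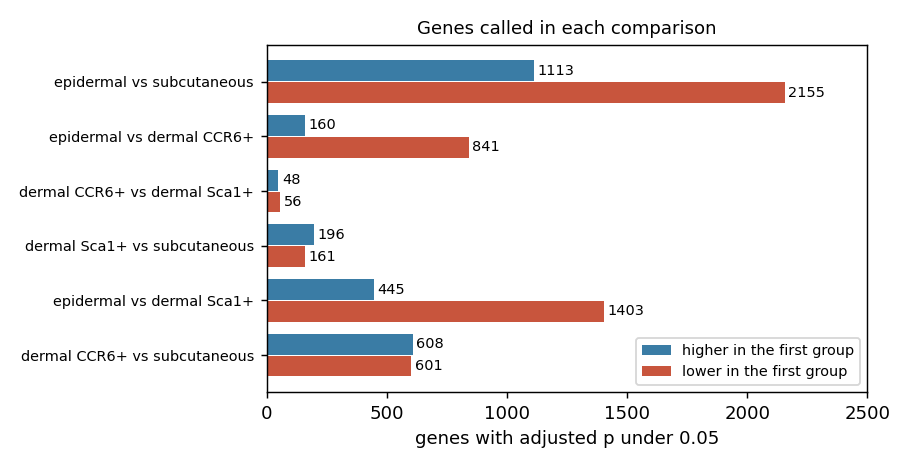
Number of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test (x axis) in each of the 6 comparisons (y axis), split by direction. The bars run from 48 higher and 56 lower genes between the dermal populations to 1113 higher and 2155 lower genes between epidermal and subcutaneous ILCs.

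The comparison of epidermal with subcutaneous ILCs set the outermost layer against the deepest. Subcutaneous ILCs had more Il5, the gene of a cytokine that sustains eosinophils, at 2774 ± 380 CPM against 95.4 ± 41.3 in epidermal ILCs (n = 3 each), and Il1rl1, which encodes the IL-33 receptor, was at 872 ± 46.0 against 1.16 ± 2.0 CPM. Klrg1, a marker of activated type 2 ILCs, was at 830 ± 214 against 0.628 ± 0.247 CPM, and the arginine-degrading enzyme gene Arg1 at 757 ± 132 against 21.1 ± 1.81 CPM. Epidermal ILCs had more of the lymphotoxin gene Lta (137 ± 3.85 against 6.07 ± 4.53 CPM) and more of the IL-18 receptor gene Il18r1 (189 ± 15 against 13.6 ± 8.90 CPM). Krt10, a keratin of the epidermis, was higher in the epidermal libraries, and Col3a1 and Lyz2, which fibroblasts and macrophages express, were higher in the subcutaneous libraries.

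In edgeR's quasi-likelihood test, 3268 of 16208 genes differed between epidermal and subcutaneous ILCs, 1113 higher and 2155 lower in the epidermis. Of those higher in epidermal ILCs by the naming rule, Calm4, Krtdap, Krt77, Krt1, Lor, Bbox1, Psapl1 and Them5 had log2 fold changes of 9.24 to 12.21, with Krtdap at 1317 ± 929 and Krt77 at 1182 ± 698 CPM. The epidermal protease gene Klk7, the cell adhesion gene Cdsn and the protease inhibitor gene Spink5 had 1 to 3 counts over the subcutaneous libraries. Their ratios were 7160 (95% exact Poisson interval 1290 to 283000), 3410 (944 to 28100) and 6430 (1150 to 254000). Among those lower in epidermal ILCs, Lyz2, Col3a1, Retnla, Gpx3, C1qb, Fabp4, F13a1 and Ccl7 had log2 fold changes of -14.94 to -10.88, with the lysozyme gene Lyz2 at 3193 ± 1160 and the collagen gene Col3a1 at 1474 ± 296 CPM in subcutaneous ILCs. Krt8, a keratin of simple epithelia on chromosome 15, 101996698 to 102004482 (mm10), had no count in the epidermal libraries and was at least 13464-fold higher in subcutaneous ILCs at 762 ± 569 CPM. Krt19, another such keratin, and the leukotriene synthesis gene Alox5 had ratios of 18800 (5210 to 155000) and 31500 (5660 to 1250000). Keratins are a family of similar genes, and reads may be split between them. None of the calls of genes named here for this comparison was lost when any 1 library was left out, and the 1113 higher genes became 698 without epidermal replicate 3. In limma on log2(TPM + 1), 47.9% of the called genes were higher in epidermal ILCs against 34.1% in edgeR, and the median log2 fold change of all genes was 0.08 against -0.02.

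Of the 25 measured type 2 ILC genes, 15 were lower in epidermal ILCs, 3 were higher and 7 were not called (15 lower and 5 higher adjusted over the list alone). The list was lower by camera (adjusted p = 0.00052, and adjusted p = 0.17 with an estimated correlation). Besides Il5, Il1rl1, Klrg1 and Arg1, the lower members included Gata3, the master transcription factor of type 2 ILCs (517 ± 27.7 against 1602 ± 362 CPM), Rora, Areg, Csf2 and Il2ra, with log2 fold changes of -4.22 to -1.32. The higher members included the IL-25 receptor gene Il17rb (105 ± 40.1 against 18.0 ± 2.06 CPM) and the prostaglandin D2 receptor gene Ptgdr2 (18.7 ± 3.55 against 0.537 ± 0.861 CPM). Of the 22 type 3 ILC genes, 4 were higher, 5 were lower and 13 were not called (6 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.76). Lta and Ccr6 were among the higher members, and Tnfsf11, Tmem176b and Nrp1 among the lower. Of the 19 type 1 ILC and NK cell genes, 4 were lower, 0 were higher and 15 were not called (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.76). Their summed level was 1641 CPM in subcutaneous replicate 2, but 204.2 and 144.9 in subcutaneous replicates 1 and 3, below the 403.9 to 483.4 of the epidermal libraries. One of the lower was the chemokine gene Ccl5 at 3.84 ± 1.17 against 86.5 ± 95.6 CPM. In the same libraries the lists of fibroblast, endothelial, macrophage and mast cell genes were also lower in the epidermal group, and the keratinocyte list was higher (adjusted p of 0.17 to 0.2 with an estimated correlation).

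Transcripts of other cell types moved with the layer. Of the 18 keratinocyte genes, 16 were higher in epidermal ILCs and 2 were not called (16 adjusted over the list alone; camera adjusted p = 5.9e-14, and adjusted p = 0.17 with an estimated correlation). Their summed level was 3894 CPM in epidermal replicate 1, against 10030 and 9846 in replicates 2 and 3 and 298.3 to 574.3 in the subcutaneous libraries. Krt10 was at 1005 ± 152 against 2.91 ± 0.461 CPM, Krt15 at 810 ± 384 against 2.13 ± 1.21 and Krt14 at 697 ± 340 against 17.7 ± 3.10. All 14 fibroblast genes were lower in epidermal ILCs, also adjusted over the list alone (camera adjusted p = 4e-12, and adjusted p = 0.18 with an estimated correlation). Dcn was at 1.97 ± 3.40 against 595 ± 173 CPM. All 10 endothelial genes were lower, also adjusted over the list alone (camera adjusted p = 3.3e-10, and adjusted p = 0.19 with an estimated correlation), and Plvap was at least 2501-fold higher in subcutaneous ILCs at 142 ± 39.6 CPM. Of the 16 macrophage, dendritic cell and Langerhans cell genes, 14 were lower and 2 were not called (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 8.2e-10, and adjusted p = 0.2 with an estimated correlation). One of them, the antigen presentation gene Cd74, was at 447 ± 43.9 against 2270 ± 592 CPM. Of the 9 mast cell and basophil genes, 7 were lower and 2 were not called (8 adjusted over the list alone; camera adjusted p = 6.6e-06, and adjusted p = 0.17 with an estimated correlation). The mast cell protease gene Cpa3 was at 105 ± 17.7 CPM in subcutaneous ILCs and a ratio of 5570 over epidermal ILCs (95% exact Poisson interval 1000 to 220000). Of the 9 adipocyte genes, 6 were lower, 1 was higher and 2 were not called, and the list alone gave the same counts (camera adjusted p = 0.00054, and adjusted p = 0.27 with an estimated correlation).

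Of the 5 neutrophil genes, 3 were lower in epidermal than in subcutaneous ILCs and 2 were not called, and the list alone gave the same count (camera adjusted p = 0.00012, and adjusted p = 0.17 with an estimated correlation). The lactoferrin gene Ltf, which glandular epithelia also express, was at least 3663-fold higher in subcutaneous ILCs at 207 ± 15.2 CPM. Of the 9 B cell genes, 5 were lower and 4 were not called (6 adjusted over the list alone; camera adjusted p = 0.00072, and adjusted p = 0.27 with an estimated correlation). Of the 13 sebocyte genes, 3 were higher, 2 were lower and 8 were not called (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.26), with the fatty acid elongase gene Elovl4 higher and the cholesterol esterification gene Soat1 lower. Of the 6 melanocyte genes, Mitf was lower and 5 were not called (2 lower adjusted over the list alone; camera adjusted p = 0.96), and Mitf is also expressed by mast cells. Of the 20 T cell genes, 3 were higher, 2 were lower and 15 were not called (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.46). They included the signalling gene Ubash3a (131 ± 6.10 against 13.6 ± 1.30 CPM) and the T cell receptor delta segment Trdv4 (41.0 ± 5.02 against 17.5 ± 2.80 CPM), both higher in epidermal ILCs, and the costimulatory receptor gene Cd28, which was lower.

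Genes of migration, secretion and cytokine reception also differed between epidermal and subcutaneous ILCs. Of the 28 secreted cytokine and chemokine genes, 16 were lower in epidermal ILCs, 1 was higher and 11 were not called (18 lower and 3 higher adjusted over the list alone; camera adjusted p = 5.9e-05, and adjusted p = 0.27 with an estimated correlation). The growth factor genes Csf1 (5.56 ± 0.277 against 141 ± 37.1 CPM) and Lif (4.99 ± 0.656 against 132 ± 45.3 CPM) were among the lower. Of the 27 chemokine receptor and homing genes, 5 were higher, 11 were lower and 11 were not called (5 higher and 13 lower adjusted over the list alone; camera adjusted p = 0.093). The higher members included Itgae, the CD103 integrin chain that binds E-cadherin (1611 ± 1063 against 12.2 ± 19.4 CPM), and Cx3cr1 (189 ± 14.7 against 5.38 ± 4.34 CPM). The lower members included S1pr1, which guides lymphocyte egress, Itga4 and Ccr2, with log2 fold changes of -6.11 to -4.04. Of the 29 cytokine receptor genes, 5 were higher, 8 were lower and 16 were not called (6 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.84). Il18r1 and the decoy receptor gene Il1r2 were higher by log2 fold changes of 3.79 ± 0.437 and 3.63 ± 0.345 (SE), and Il4ra and Ifngr1 were lower by -3.42 ± 0.356 and -2.10 ± 0.217. Of the 16 TNF superfamily ligand genes, 3 were higher, 4 were lower and 9 were not called (5 each adjusted over the list alone; camera adjusted p = 0.78). Cd70 was at 55.2 ± 8.26 against 2.21 ± 0.548 CPM. The fibroblast, endothelial, macrophage and mast cell lists were lower in the same epidermal libraries (adjusted p of 0.17 to 0.2 with an estimated correlation), and such cells also express several of these cytokines and receptors.

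Among the lists of cell state, interferon response, NF-kB target and immediate early genes were lower in epidermal than in subcutaneous ILCs, and cell cycle and cholesterol synthesis genes were higher. Of the 22 interferon response genes, 17 were lower and 5 were not called (19 adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.17 with an estimated correlation). Isg15 was at 5.84 ± 1.75 against 69.8 ± 15.3 CPM and Rsad2 at 0.818 ± 0.732 against 59.4 ± 26.9. Of the 18 NF-kB target genes, 10 were lower and 8 were not called (14 adjusted over the list alone; camera adjusted p = 4.9e-05, and adjusted p = 0.31 with an estimated correlation). Epidermal replicate 1 stood apart with a summed level of 9490 CPM, against 4037 and 3629 in replicates 2 and 3 and 12230 to 19320 in the subcutaneous libraries. Of the 21 immediate early and heat shock genes, 15 were lower, 1 was higher and 5 were not called (18 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.3e-06, and adjusted p = 0.37 with an estimated correlation). Their summed level was 13980 CPM in epidermal replicate 1 against 8485 and 8201 in replicates 2 and 3, and 29190 CPM in subcutaneous replicate 1 against 17420 and 21810 in replicates 2 and 3. Egr1 was at 152 ± 5.84 against 551 ± 107 CPM. Of the 20 cell cycle genes, 9 were higher and 11 were not called (12 adjusted over the list alone; camera adjusted p = 4.5e-06, and adjusted p = 0.36 with an estimated correlation). Subcutaneous replicate 2 had the highest summed level of cell cycle genes among its group (703.4 against 396.1 and 334.8 CPM), of interferon response genes (1947 against 1037 and 1363 CPM) and of macrophage genes (12930 against 8522 and 7186 CPM). The mitotic gene Ube2c was at 41.5 ± 14.7 against 9.30 ± 4.79 CPM. Of the 22 cholesterol synthesis genes, 12 were higher and 10 were not called (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.7e-06, and adjusted p = 0.17 with an estimated correlation). Sqle was at 134 ± 22.5 against 36.9 ± 12.8 CPM. In the same epidermal libraries the keratinocyte list was higher (camera adjusted p = 5.9e-14, and adjusted p = 0.17 with an estimated correlation). All 14 fibroblast, all 10 endothelial and 14 of 16 macrophage genes were lower there (adjusted p of 0.18 to 0.2 with an estimated correlation), and such cells also express genes of these lists.

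Of the 17 glycolysis genes, 4 were higher in epidermal than in subcutaneous ILCs, 3 were lower and 10 were not called, and the list alone gave the same counts (camera adjusted p = 0.32). The triose phosphate isomerase gene Tpi1 was higher and the glucose transporter gene Slc2a3 lower. Of the 19 genes for receptors of neuropeptides, hormones and lipid mediators, 6 were higher, 7 were lower and 6 were not called (7 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.83). The prostaglandin E2 receptor gene Ptger4 was at 340 ± 96.5 against 70.9 ± 20.4 CPM, and Ramp3, a partner of the calcitonin receptor-like receptor, was at 4.74 ± 1.84 against 222 ± 35.4 CPM. Of the 18 Notch pathway genes, 2 were higher, 2 were lower and 14 were not called (3 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.32), with the ligand gene Jag1 higher and Notch2 lower. Median, mean and camera direction did not share 1 sign for the uncalled lists of type 3 ILC, T cell, melanocyte, TNF ligand, glycolysis and receptor genes.

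**Figure D3:**
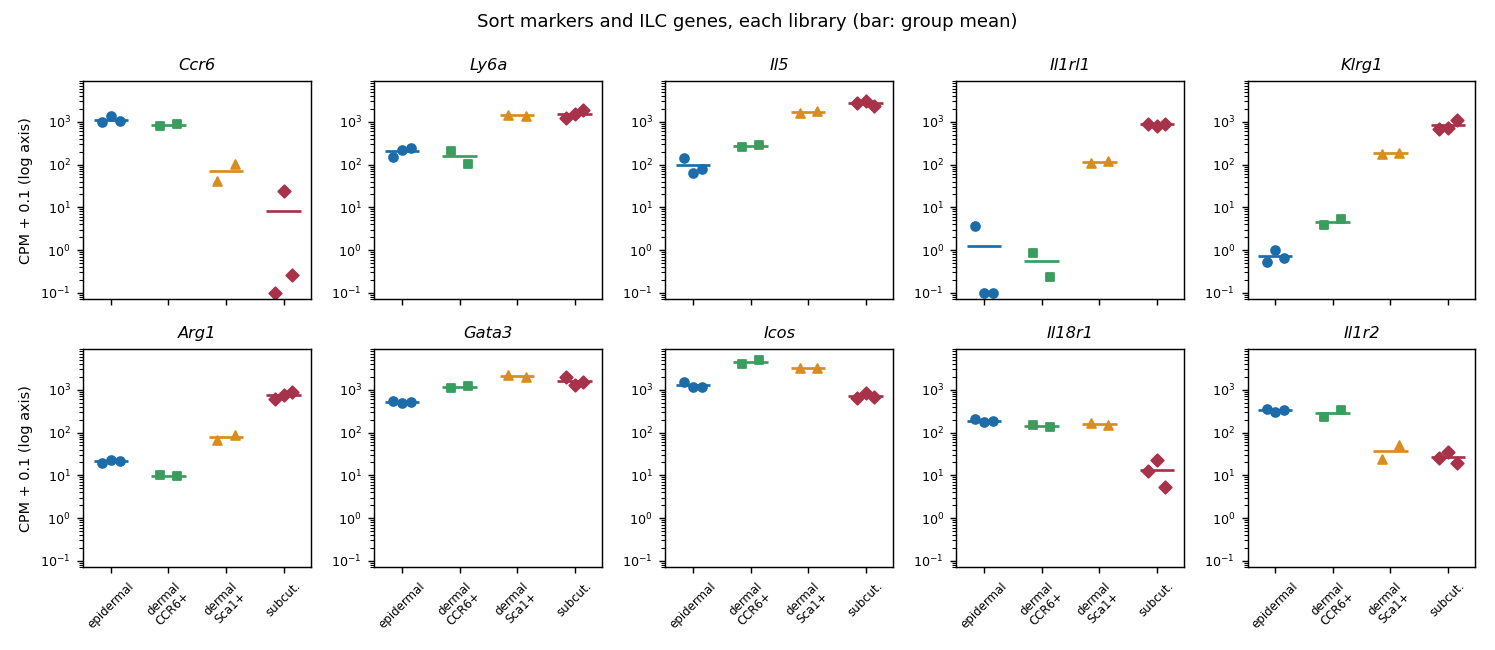
CPM + 0.1 (y axis, log scale) of 10 genes in each library by group (x axis), with points for libraries and bars for group means. Il5, Il1rl1 and Klrg1 are highest in the 3 subcutaneous libraries, and Ccr6 and Il1r2 are high in the 3 epidermal and 2 dermal CCR6+ libraries.

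Epidermal ILCs were next compared with dermal CCR6+ ILCs, the dermal population that shared the high Ccr6 level. Most genes that differed were lower in the epidermis. They included Gata3 (517 ± 27.7 against 1162 ± 111 CPM, n = 3 and n = 2), the costimulatory receptor gene Icos (1293 ± 221 against 4460 ± 710 CPM), Rora (847 ± 71.5 against 2512 ± 4.13 CPM) and the IL-2 receptor beta chain gene Il2rb (580 ± 109 against 1821 ± 129 CPM). The receptor genes Il4ra and Ifngr1 were lower by log2 fold changes of -2.98 ± 0.368 and -2.16 ± 0.232 (SE), and Ramp3 by -5.90 ± 0.332. Lor and Krt10, which keratinocytes express, were higher in the epidermal libraries, and Col3a1 and Plvap, which fibroblasts and endothelial cells express, were lower.

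In edgeR's quasi-likelihood test, 1001 genes differed between epidermal and dermal CCR6+ ILCs, 160 higher and 841 lower in the epidermis. Those higher by the naming rule were Serpinb7, Flg2, Cdsn, Spink5, Hal, Esrp1, Ppl and Orm1, with log2 fold changes of 4.48 to 9.14. Lor, Lce1m and Kprp, genes of the cornified envelope, had no count in the dermal CCR6+ libraries and were at least 1509-fold, 1041-fold and 972-fold higher. Lce1m belongs to a cluster of similar genes that can share reads. Those lower were Col3a1, Lyz2, Fabp4, Aqp1, Col1a2, Gatm, Rarres2 and Igfbp5, with log2 fold changes of -11.62 to -8.13. The endothelial gene Plvap and the fatty acid transporter gene Cd36 had no count in the epidermal libraries and were at least 2135-fold and 1396-fold higher in dermal CCR6+ ILCs, and Sparcl1 had a ratio of 3320 (95% exact Poisson interval 597 to 131000). The share of called genes that were higher in epidermal ILCs was 16.0% in edgeR, 29.2% in DESeq2 and 35.6% in limma on log2(TPM + 1). The 160 higher genes became 59 (7.4%) without dermal CCR6+ replicate 2, and 78 (10.6%) and 72 (9.8%) without epidermal replicates 2 and 3. Leaving out 1 library ended calls of several of the named genes, where a lone dermal library was assumed to vary like the other groups. Without dermal CCR6+ replicate 1 these were Hal, Lce1m, Orm1, Ppl, Cdsn, Spink5 and Serpinb7, and the same genes except Spink5 lost their calls without dermal CCR6+ replicate 2, with edgeR adjusted p up to 0.186 and 0.196. Without epidermal replicate 2 they were Hal, Orm1, Ppl, Cdsn, Esrp1 and Serpinb7, and the same genes except Ppl without epidermal replicate 3, with edgeR adjusted p up to 0.12 and 0.127. Esrp1 also lost its call without epidermal replicate 1, without either dermal Sca1+ library and without each subcutaneous library, Cdsn without each subcutaneous library and Orm1 without dermal Sca1+ replicate 1, with edgeR adjusted p of 0.0527 to 0.0758. A fit of these 2 groups alone ended the call of Esrp1 as well (edgeR adjusted p = 0.0971).

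Of the 25 type 2 ILC genes, 9 were lower in epidermal than in dermal CCR6+ ILCs, 3 were higher and 13 were not called (9 lower and 4 higher adjusted over the list alone; camera adjusted p = 0.13). Their median lay above 0, and their mean and the camera direction below it. The lower members included Gata3, Rora, Icos and the growth factor gene Areg, a ligand of the EGF receptor (56.1 ± 31.6 against 239 ± 8.29 CPM). The higher members included Il13 (42.6 ± 4.63 against 12.3 ± 2.52 CPM) and Arg1 (21.1 ± 1.81 against 9.70 ± 0.176 CPM), both of whose calls were lost without either dermal CCR6+ library, and that of Arg1 also in a fit of these 2 groups alone (edgeR adjusted p of 0.0527 to 0.196 without 1 of these libraries over all genes named for this comparison). Of the 22 type 3 ILC genes, 1 was higher, 1 was lower and 20 were not called, and the list alone gave the same counts (camera adjusted p = 0.56). Of the 29 cytokine receptor genes, 5 were lower and 24 were not called (8 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.52 with an estimated correlation). Of the 27 chemokine receptor and homing genes, 4 were lower, 1 was higher and 22 were not called (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0098, and adjusted p = 0.46 with an estimated correlation). S1pr1 was at 6.12 ± 2.33 against 77.7 ± 21.4 CPM and its transcription factor gene Klf2 at 12.7 ± 2.57 against 65.0 ± 13.8 CPM. Of the 18 NF-kB target genes, 6 were lower and 12 were not called, and the list alone gave the same count (camera adjusted p = 1.6e-05, and adjusted p = 0.27 with an estimated correlation). Their summed level in epidermal replicate 1, 9490 CPM, lay within the 9162 to 9778 of the dermal CCR6+ libraries. Traf1 was at 142 ± 7.71 against 603 ± 189 CPM. Of the 21 immediate early and heat shock genes, 7 were lower and 14 were not called (8 adjusted over the list alone; camera adjusted p = 0.00012, and adjusted p = 0.44 with an estimated correlation). In epidermal replicates 1, 2 and 3 their summed level was 13980, 8485 and 8201 CPM, against 15620 and 16140 in the dermal CCR6+ libraries. Ier3 was at 3.94 ± 0.424 against 59.6 ± 43.3 CPM. Of the 17 glycolysis genes, 3 were lower and 14 were not called (6 adjusted over the list alone; camera adjusted p = 0.024, and adjusted p = 0.56 with an estimated correlation). The fibroblast, endothelial, macrophage and mast cell lists were lower in the same epidermal libraries (adjusted p of 0.17 to 0.23 with an estimated correlation).

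Of the 18 keratinocyte genes, 5 were higher in epidermal than in dermal CCR6+ ILCs and 13 were not called (7 adjusted over the list alone; camera adjusted p = 4.9e-05, and adjusted p = 0.35 with an estimated correlation). Their summed level in epidermal replicate 1, 3894 CPM, lay near the 3069 and 2159 of the dermal CCR6+ libraries and below the 10030 and 9846 of epidermal replicates 2 and 3. Krt10 was at 1005 ± 152 against 81.7 ± 8.85 CPM. Of the 14 fibroblast genes, 12 were lower and 2 were not called (13 adjusted over the list alone; camera adjusted p = 1.2e-14, and adjusted p = 0.17 with an estimated correlation). Dcn was at 1.97 ± 3.40 against 275 ± 112 CPM and Col1a1 at 2.31 ± 2.28 against 435 ± 188 CPM. All 10 endothelial genes were lower, also adjusted over the list alone (camera adjusted p = 1.2e-14, and adjusted p = 0.17 with an estimated correlation). Of the 16 macrophage, dendritic cell and Langerhans cell genes, 9 were lower and 7 were not called (15 adjusted over the list alone; camera adjusted p = 5.4e-09, and adjusted p = 0.23 with an estimated correlation). H2-Ab1 was at 44.8 ± 2.98 against 280 ± 31.5 CPM. Of the 9 mast cell and basophil genes, 5 were lower and 4 were not called (7 adjusted over the list alone; camera adjusted p = 8.5e-06, and adjusted p = 0.17 with an estimated correlation), with a ratio of 503 for Cpa3 (95% exact Poisson interval 90.2 to 19900). Of the 13 sebocyte genes, 3 were lower and 10 were not called (5 adjusted over the list alone; camera adjusted p = 0.0043, and adjusted p = 0.41 with an estimated correlation).

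**Figure D4:**
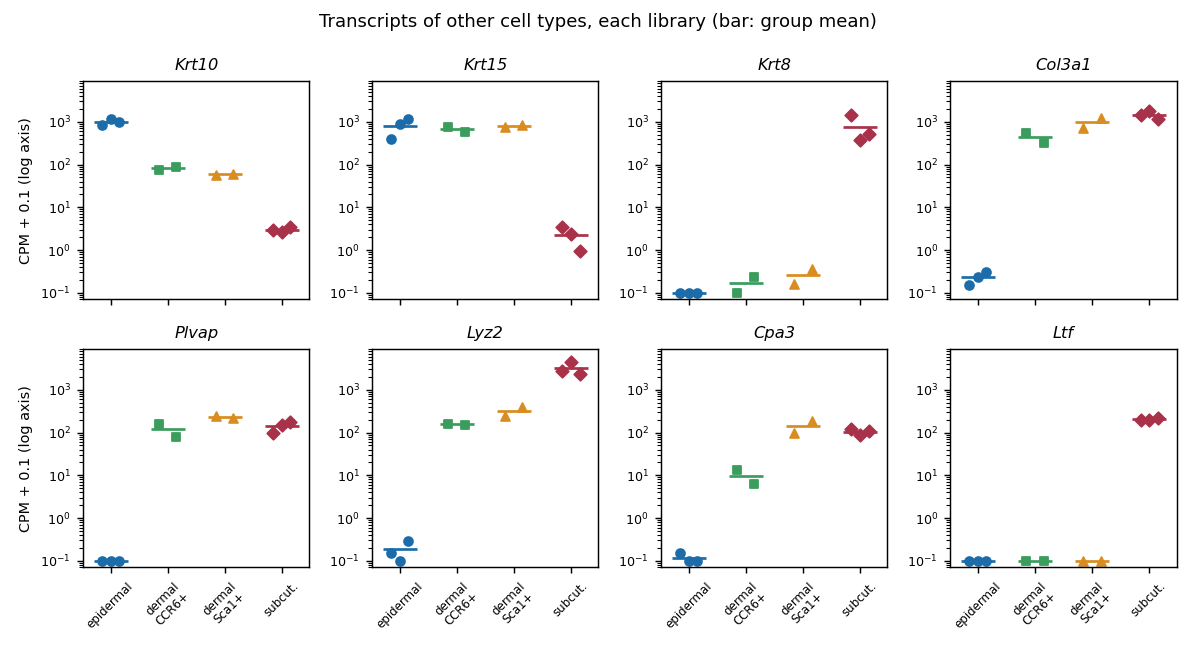
CPM + 0.1 (y axis, log scale) of 8 transcripts of other cell types in each library by group (x axis), with points for libraries and bars for group means. Krt10 is highest in the 3 epidermal libraries, Col3a1, Plvap, Lyz2 and Cpa3 are near the floor there, and Krt8 and Ltf are high in the 3 subcutaneous libraries alone.

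The comparison of dermal CCR6+ with dermal Sca1+ ILCs set both sorted populations of 1 layer against each other. Sca1+ ILCs had more Klrg1, Arg1, Il5 and Il2ra. Klrg1 was at 183 ± 7.49 against 4.44 ± 1.10 CPM in CCR6+ ILCs (n = 2 each), Arg1 at 77.6 ± 14.1 against 9.70 ± 0.176 CPM, Il5 at 1716 ± 95.9 against 273 ± 19.9 CPM and the IL-2 receptor alpha chain gene Il2ra at 455 ± 8.87 against 100 ± 6.84 CPM. They also had more of the integrin gene Itga4 (164 ± 39.7 against 5.75 ± 0.852 CPM) and of the growth factor gene Csf1 (53.1 ± 7.61 against 7.13 ± 0.0887 CPM). CCR6+ ILCs had more Tff1, a trefoil peptide gene (66.2 ± 19.4 against 0.387 ± 0.547 CPM), and more Ubash3a (90.1 ± 12.9 against 10.8 ± 5.88 CPM). Vipr2, a receptor for vasoactive intestinal peptide, was at 37.1 ± 20.4 CPM in CCR6+ ILCs and had no count in Sca1+ ILCs.

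In edgeR's quasi-likelihood test, 104 genes differed between the dermal populations, 48 higher and 56 lower in CCR6+ ILCs. Those higher by the naming rule were Tff1, Tnfrsf8, Rnf208, Arnt2, Ryr1, Pmepa1, the inhibitory receptor gene Ctla4 and the hair keratin gene Krt83, with log2 fold changes of 3.21 to 7.54. The acid-sensing channel gene Asic3 and Vipr2 were at least 485-fold and 338-fold higher, and Apol9b, which has a close paralog that can share reads, had a ratio of 656 (95% exact Poisson interval 118 to 25900). Those lower were Il1rl1, Dach2, Klrg1, Itga4, Gimap3, Spry2, Hs3st1 and Cpa3, with log2 fold changes of -7.95 to -3.92, and Gimap3 has similar neighbours that can share reads. Without dermal CCR6+ replicate 1, 38 genes were higher and 117 lower. The number of genes was 35 without dermal CCR6+ replicate 2, and 43 and 51 without dermal Sca1+ replicates 1 and 2, where the lone library was assumed to vary like the other groups. Of the named genes, Rnf208, Tff1, Pmepa1, Krt83, Asic3, Vipr2, Apol9b, Klrg1, Itga4, Hs3st1, Arg1, Il2ra, Csf1 and Ubash3a were called without any 1 library. A fit of these 2 groups alone ended the calls of Csf1, Vipr2, Apol9b, Tff1 and Ubash3a among them (edgeR adjusted p = 0.0507 for Csf1, 0.0522 for Vipr2 and Apol9b, and 0.076 for the others). It also ended those of Ly6a, Cpa3, Gimap3, Tnfrsf8 and Spry2 (edgeR adjusted p of 0.0507 to 0.195). An offset for gene length ended the calls of Arnt2 and Il1rl1, and limma on log2(TPM + 1) those of Arnt2 and Ryr1. Without dermal CCR6+ replicate 2, calls ended for Cpa3, Arnt2, Spry2, Dach2, Ctla4, Il1rl1, Tnfrsf8, Ryr1, Il5 and Gimap3 (edgeR adjusted p up to 0.335), and without dermal CCR6+ replicate 1 for Arnt2, Il1rl1, Ryr1 and Gimap3 (up to 0.121). Without dermal Sca1+ replicate 1 they ended for Arnt2, Spry2, Ctla4, Il1rl1, Tnfrsf8, Ryr1 and Gimap3 (up to 0.155), and without dermal Sca1+ replicate 2 for the same genes except Tnfrsf8 (up to 0.179). Without single libraries of the other layers, edgeR adjusted p between 0.0512 and 0.0821 ended calls of Tnfrsf8 (each epidermal library), Il1rl1 and Spry2 (each subcutaneous library), Gimap3 (subcutaneous replicates 1 and 3) and Ctla4 (subcutaneous replicate 1).

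Of the 25 type 2 ILC genes, 7 were lower in dermal CCR6+ than in dermal Sca1+ ILCs, 0 were higher and 18 were not called (11 lower and 2 higher adjusted over the list alone). The list was lower by camera (adjusted p = 1.5e-06, and adjusted p = 0.17 with an estimated correlation). None of the 22 type 3 ILC genes was called over all genes, and 3 were higher adjusted over the list alone, while the list was higher by camera (adjusted p = 0.00068, and adjusted p = 0.27 with an estimated correlation). That list includes Ccr6, the gene of the marker by which the CCR6+ ILCs were sorted. Part of its difference therefore follows from the sort, and the list without Ccr6 was not tested. Of the 28 secreted cytokine and chemokine genes, 5 were lower and 23 were not called (9 lower and 3 higher adjusted over the list alone). Their median and the camera test lay below 0 while their mean lay above it (camera adjusted p = 0.001, and adjusted p = 0.35 with an estimated correlation). No gene of the cell cycle list was called, also adjusted over the list alone, while the list was higher in CCR6+ ILCs by camera (adjusted p = 0.00015, and adjusted p = 0.44 with an estimated correlation). The TNF ligand gene Tnfsf8 and the decoy receptor gene Il1r2 were higher in CCR6+ ILCs, at 110 ± 7.25 against 17.5 ± 10.6 CPM and 286 ± 73.8 against 37.9 ± 20.3 CPM. Both calls ended without dermal CCR6+ replicate 2 and without dermal Sca1+ replicate 1, and that of Tnfsf8 also without dermal CCR6+ replicate 1, and a fit of these 2 groups alone ended both as well (edgeR adjusted p of 0.0513 to 0.335 over the genes named for this comparison).

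Lists of other cell types were also tested between the dermal populations. Of the 9 mast cell and basophil genes, 1 was lower in CCR6+ ILCs and 8 were not called (3 adjusted over the list alone; camera adjusted p = 1.3e-05, and adjusted p = 0.17 with an estimated correlation). Cpa3 was at 9.49 ± 4.92 against 144 ± 63.7 CPM. Mast cells express Il1rl1 as well. No gene of the fibroblast, macrophage or endothelial lists was called, also adjusted over each list alone, while camera placed the lists lower in CCR6+ ILCs (adjusted p = 0.0039, 0.0021 and 0.014, and adjusted p = 0.52, 0.48 and 0.56 with an estimated correlation). The summed level of the macrophage list was 1693 and 1982 CPM in the CCR6+ libraries, 1784 in Sca1+ replicate 1 and 3922 in Sca1+ replicate 2, so that only Sca1+ replicate 2 lay above both CCR6+ libraries. No keratinocyte gene was called, also adjusted over the list alone (camera adjusted p = 0.96). Of the 9 B cell genes, 1 was lower and 8 were not called (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.57). It was the immunoglobulin gene Ighm, at 12.4 ± 5.18 against 172 ± 4.95 CPM, whose call ended without any 1 dermal or subcutaneous library (edgeR adjusted p of up to 0.317).

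The comparison of dermal Sca1+ with subcutaneous ILCs set against each other the populations with a high Ly6a level. Il5 was at 1716 ± 95.9 and 2774 ± 380 CPM (n = 2 and n = 3) and Il1rl1 at 115 ± 5.59 and 872 ± 46.0 CPM, and neither difference passed the test (edgeR adjusted p = 0.31 and 0.195). Subcutaneous ILCs had more Arg1 (757 ± 132 against 77.6 ± 14.1 CPM), more Klrg1 (830 ± 214 against 183 ± 7.49 CPM) and more Tmem176b (1476 ± 314 against 300 ± 86.3 CPM). Dermal Sca1+ ILCs had more Icos (3180 ± 19.8 against 723 ± 101 CPM) and more Il18r1 (158 ± 8.11 against 13.6 ± 8.90 CPM). The keratin genes Krt15, Krt1 and Krt79 were higher in the dermal libraries, and Krt8, Krt18 and Krt19 in the subcutaneous libraries.

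In edgeR's quasi-likelihood test, 357 genes differed between dermal Sca1+ and subcutaneous ILCs, 196 higher and 161 lower in dermal ILCs. Those higher by the naming rule were Krt15, Calm4, Psapl1, Fgfbp1, Aadac, Krt1, Krt79 and Elovl4, with log2 fold changes of 7.58 to 8.56 and Krt15 at 813 ± 63.5 against 2.13 ± 1.21 CPM. Cyp2g1 and the transglutaminase gene Tgm5 had no count in the subcutaneous libraries and were at least 3674-fold and 1057-fold higher, and Serpina3b had a ratio of 5880 (95% exact Poisson interval 1060 to 232000). Those lower were Krt8, Krt18, Krt19, Fcna, Wfdc2, Enpep, Cldn4 and Cd209f, with log2 fold changes of -12.26 to -6.37, and Krt8 and Krt18 are keratins that pair with each other. Dmbt1, the haemoglobin gene Hbb-bs and Ltf had no count in dermal Sca1+ ILCs and were at least 3573-fold, 2444-fold and 1892-fold higher in subcutaneous ILCs, and Hbb-bs has a close paralog that can share reads. The share of called genes that were higher in dermal Sca1+ ILCs was 54.9% in edgeR, 40.8% in DESeq2, 40.0% in limma on log2(TPM + 1) and 35.7% in a fit of these 2 groups alone. The number of genes was 157 and 219 without dermal Sca1+ replicates 1 and 2, where the lone library was assumed to vary like the other groups, and 188, 218 and 191 without subcutaneous replicates 1, 2 and 3. Of the named genes, calls ended for Fcna, Klrg1, Enpep, Cldn4, Dmbt1, Cd209f and Hbb-bs without dermal Sca1+ replicate 1 (edgeR adjusted p up to 0.115), and for the last 5 of these without dermal Sca1+ replicate 2 (up to 0.134). They ended for Enpep and Cldn4 also without each subcutaneous library, for Hbb-bs and Cyp2g1 without subcutaneous replicates 1 and 3, for Wfdc2 without subcutaneous replicate 1, for Serpina3b without subcutaneous replicate 3 and for Cldn4 without epidermal replicate 3 (edgeR adjusted p of 0.0506 to 0.118).

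Of the 25 type 2 ILC genes, 7 were lower in dermal Sca1+ than in subcutaneous ILCs, 2 were higher and 16 were not called (9 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.18). Of the 22 type 3 ILC genes, 3 were lower and 19 were not called (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.06). Of the 28 secreted cytokine and chemokine genes, 3 were lower and 25 were not called (8 adjusted over the list alone; camera adjusted p = 0.00075, and adjusted p = 0.34 with an estimated correlation). Of the 22 interferon response genes, 2 were lower and 20 were not called (6 adjusted over the list alone; camera adjusted p = 5.4e-06, and adjusted p = 0.23 with an estimated correlation). Ifi27l2a was at 26.4 ± 5.07 against 208 ± 109 CPM. Of the 22 cholesterol synthesis genes, 5 were higher and 17 were not called (8 adjusted over the list alone; camera adjusted p = 3.9e-06, and adjusted p = 0.17 with an estimated correlation), with a log2 fold change of 1.98 ± 0.327 (SE) for Msmo1. The egress transcription factor gene Klf2 was lower at 81.6 ± 17.2 against 284 ± 33.3 CPM. Single libraries ended the calls of Ifi27l2a (dermal Sca1+ replicate 1), Klf2 (dermal Sca1+ replicate 2) and Msmo1 (dermal Sca1+ replicate 2 and subcutaneous replicate 1), with edgeR adjusted p between 0.0524 and 0.134. The keratinocyte and sebocyte lists, whose cells also make cholesterol, were higher in the same dermal libraries, and the macrophage list was lower (adjusted p = 0.17, 0.25 and 0.41 with an estimated correlation).

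Of the 18 keratinocyte genes, 12 were higher in dermal Sca1+ than in subcutaneous ILCs and 6 were not called (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.6e-16, and adjusted p = 0.17 with an estimated correlation). Krt14 was at 415 ± 169 against 17.7 ± 3.10 CPM and Krt10 at 58.6 ± 3.31 against 2.91 ± 0.461. Of the 13 sebocyte genes, 5 were higher and 8 were not called (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 9e-06, and adjusted p = 0.25 with an estimated correlation). The fatty acid desaturase gene Scd1 was at 643 ± 235 against 67.0 ± 18.8 CPM. Of the 16 macrophage, dendritic cell and Langerhans cell genes, 2 were lower and 14 were not called (9 adjusted over the list alone; camera adjusted p = 0.00026, and adjusted p = 0.41 with an estimated correlation). Lyz2 was at 322 ± 105 against 3193 ± 1160 CPM. Of the 5 neutrophil genes, 2 were lower and 3 were not called (5 adjusted over the list alone; camera adjusted p = 3.3e-10, and adjusted p = 0.17 with an estimated correlation). Of the 9 B cell genes, 2 were lower and 7 were not called (4 adjusted over the list alone; camera adjusted p = 2.4e-06, and adjusted p = 0.17 with an estimated correlation). No endothelial or fibroblast gene was called, also adjusted over each list alone (camera adjusted p = 0.82 and 0.094), and the endothelial mean lay below 0 while the camera direction was up.

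Both secondary comparisons crossed the sort markers and layers. Against dermal Sca1+ ILCs, epidermal ILCs had less Gata3 (517 ± 27.7 against 2111 ± 148 CPM), less Il5 (95.4 ± 41.3 against 1716 ± 95.9 CPM), less Klrg1 (0.628 ± 0.247 against 183 ± 7.49 CPM) and less Il1rl1 (1.16 ± 2.0 against 115 ± 5.59 CPM). In edgeR's quasi-likelihood test 1848 genes differed, 445 higher and 1403 lower in the epidermis. The share that was higher was 24.1% in edgeR and 39.1% in limma on log2(TPM + 1). The number of genes was 1199 and 1192 without dermal Sca1+ replicates 1 and 2, and the higher genes became 243 without epidermal replicate 3. Those higher by the naming rule were Tff1, Kprp, Skint10 and Dsg1b, with log2 fold changes of 6.88 to 7.85, Lor with a ratio of 2020 (95% exact Poisson interval 558 to 16600) and Lce1m, at least 927-fold higher. Those lower were Col3a1, Lyz2, Fabp4 and Aqp1, with log2 fold changes of -12.75 to -9.77, Plvap, at least 4123-fold lower, and Cpa3 with a ratio of 7630 (1370 to 301000) for Sca1+ over epidermal ILCs. The calls of Dsg1b and Kprp ended without dermal Sca1+ replicate 1 and replicate 2 respectively (edgeR adjusted p = 0.0718 and 0.0572), and Kprp was not called in DESeq2 either. Of the 25 type 2 ILC genes, 15 were lower, 2 were higher and 8 were not called (17 lower and 3 higher adjusted over the list alone; camera adjusted p = 3.9e-06, and adjusted p = 0.17 with an estimated correlation). Of the 22 type 3 ILC genes, 4 were higher, 2 were lower and 16 were not called (7 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.038, and adjusted p = 0.48 with an estimated correlation). In the same libraries the fibroblast list was lower (13 of 14 genes, camera adjusted p = 6e-14, and adjusted p = 0.17 with an estimated correlation), and so was the mast cell list (7 of 9 genes, camera adjusted p = 3.6e-07, and adjusted p = 0.17 with an estimated correlation).

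Against subcutaneous ILCs, dermal CCR6+ ILCs had less Il5 (273 ± 19.9 against 2774 ± 380 CPM), Klrg1 (4.44 ± 1.10 against 830 ± 214 CPM) and Arg1 (9.70 ± 0.176 against 757 ± 132 CPM), and more Il1r2 (286 ± 73.8 against 26.7 ± 8.25 CPM) and Il18r1 (145 ± 11.6 against 13.6 ± 8.90 CPM). In edgeR's quasi-likelihood test 1209 genes differed, 608 higher and 601 lower in dermal CCR6+ ILCs. The number was 435 without dermal CCR6+ replicate 2 and 769 without subcutaneous replicate 1. The share that was higher was 50.3% in edgeR, 41.4% in DESeq2, 45.4% in limma on log2(TPM + 1) and 38.7% in a fit of these 2 groups alone. The higher genes became 405 without dermal CCR6+ replicate 1, and the lower ones 377 and 399 without subcutaneous replicates 2 and 3. Those higher by the naming rule were Calm4, Krt15, Krt79 and the lymphocyte receptor gene Slamf1, with log2 fold changes of 7.90 to 8.50, Cyp2g1, at least 1316-fold higher, and Tff1 with a ratio of 1390 (95% exact Poisson interval 384 to 11500). Those lower were Krt19, Il1rl1, Wfdc18 and Krt7, with log2 fold changes of -11.77 to -8.90, Krt18, at least 6052-fold lower, and Krt8 with a ratio of 11700 (3240 to 96700) for subcutaneous over CCR6+ ILCs. Of the 25 type 2 ILC genes, 12 were lower, 4 were higher and 9 were not called, and the list alone gave the same counts (camera adjusted p = 0.0016, and adjusted p = 0.2 with an estimated correlation). Of the 22 type 3 ILC genes, 4 were higher, 4 were lower and 14 were not called, and the list alone gave the same counts (camera adjusted p = 0.6, with a camera direction of up and a median and mean below 0). Of the 17 glycolysis genes, 8 were higher, 1 was lower and 8 were not called (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.43 with an estimated correlation). Aldoa was at 1651 ± 129 against 792 ± 57.7 CPM. In the same libraries 13 of 18 keratinocyte genes were higher (camera adjusted p = 2.3e-13, and adjusted p = 0.17 with an estimated correlation) and 10 of 16 macrophage genes were lower (camera adjusted p = 3.9e-06, and adjusted p = 0.31 with an estimated correlation).

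Genes that set 1 group apart were those higher in it than in each of the other 3 groups, with an edgeR adjusted p under 0.05 in all 3 comparisons. There were 69 for epidermal ILCs, led by Lce1m, Serpina12, Wfdc21, Lor, Crct1, Il1f5, Cnfn and Flg2, at means of 25.2 to 147 CPM. Their SDs were 79.7, 48.9, 56.9, 104, 58.5, 17.1, 28.9 and 36.4 CPM in that order. Lce1m and Lor are genes of the cornified envelope, and keratinocytes express Lor. The keratinocyte list summed to 3894 to 10030 CPM in the epidermal libraries, against 298.3 to 3100 in the others. Whether these genes came from ILCs or from keratinocyte RNA was not tested. There were 119 for subcutaneous ILCs, led by Dmbt1, Ltf, Fgg, Csn3, Fgb, Aqp5, Siglec1 and Ido1, at means of 69.7 to 392 CPM and with no count in any library of the other groups. Their SDs over the subcutaneous libraries were 387, 15.2, 98.3, 34.3, 123, 25.35, 40.1 and 27.5 CPM in that order. Dmbt1, Fgg and Fgb thus varied widely within the group, with means of 392, 122 and 109 CPM. Csn3 encodes a milk casein and Siglec1 a macrophage receptor. Dermal CCR6+ ILCs had 6 such genes, Nmrk1, Ctla4, Palld, the OX40 receptor gene Tnfrsf4, Avpi1 and Ciapin1. Nmrk1 was at 127 ± 6.09 CPM against means of 10.4 to 18.9 in the other groups, and Ctla4 was at 118 ± 45.3 CPM against 10.5 to 26.5. Dermal Sca1+ ILCs had 0 such genes in edgeR's quasi-likelihood test, against 63 at an unadjusted p under 0.05 in all 3 comparisons, 10 in DESeq2 and 16 in limma on log2(TPM + 1).

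The numbers of such genes depended on single libraries. For epidermal ILCs the number was 114, 29 and 27 without epidermal replicates 1, 2 and 3, 22 and 29 without dermal CCR6+ replicates 1 and 2, and 42 and 35 without dermal Sca1+ replicates 1 and 2. For subcutaneous ILCs it was 34 and 61 without dermal Sca1+ replicates 1 and 2, and 61, 61 and 67 without subcutaneous replicates 1, 2 and 3. For dermal CCR6+ ILCs it was 11 without epidermal replicate 1, 3 and 0 without dermal CCR6+ replicates 1 and 2, and 0 and 2 without dermal Sca1+ replicates 1 and 2. For dermal Sca1+ ILCs it was 1 without epidermal replicate 1 and 1 without either dermal CCR6+ library.

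The contrast between epidermal and subcutaneous ILCs and that between dermal CCR6+ and dermal Sca1+ ILCs, which share no library, had genes in common. Both called 89 genes in the same direction. Of these, 36 were higher in epidermal and in CCR6+ ILCs, against 3.3 for independent lists of these sizes, and 53 were lower in both, against 7.4. The lists are not independent, because both contrasts were tested in 1 fit with 1 estimate of the spread per gene. Genes with a low spread are more easily called in both, so 3.3 and 7.4 are not chance levels. Arg1, Klrg1, Il5, Il2ra, Itga4 and Csf1 were lower in both, and Ubash3a and Il1r2 were higher in both. A further 2 genes were called in opposite directions. Across all tested genes, which are not independent, the log2 fold changes of both contrasts had a Pearson r of 0.219 and a Spearman rho of 0.305. Without dermal CCR6+ replicate 1, 80 genes were lower in both. The number of shared genes was 31 without dermal CCR6+ replicate 2, and 39 and 40 without dermal Sca1+ replicates 1 and 2.

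Across all 26 lists and 6 comparisons, 77 of 156 pairs passed camera with the preset correlation, 22 of them higher and 55 lower in the first group named. With an estimated correlation, camera called 0 pairs, against 31 at an unadjusted p under 0.05, and fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes, called 69.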

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

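The alternative without epidermal replicate 1 and subcutaneous replicate 1 together was chosen after seeing the data, and all others before. Both libraries are the only ones in their run of deposited numbers. Of 235 calls of named genes, 185 held under each of the 22 alternatives that gave them an adjusted p (DESeq2 gave none for 6 of the 235), 41 were lost when at least 1 single library was left out, 34 under at least 1 other alternative, and 0 changed direction. The number of genes differing between epidermal and subcutaneous ILCs stayed within 1.5 times of 3268 under every alternative run. Other counts moved further, in the order epidermal with dermal CCR6+, dermal CCR6+ with dermal Sca1+, dermal Sca1+ with subcutaneous, epidermal with dermal Sca1+, and dermal CCR6+ with subcutaneous. DESeq2 called 2001, 556, 1187, 2965 and 2345 genes, and edgeR with no filter 2028, 647, 1328, 2918 and 2292. With these settings 360 and 457 genes were shared between epidermal with subcutaneous and the contrast within the dermis, and the genes highest in epidermal, dermal CCR6+, dermal Sca1+ and subcutaneous ILCs numbered 175, 30, 10 and 367 in DESeq2 and 212, 28, 12 and 512 with no filter. Limma on log2(TPM + 1) called 891 genes between dermal Sca1+ and subcutaneous and 1978 between dermal CCR6+ and subcutaneous ILCs, with 239, 16 and 447 genes highest in epidermal, dermal Sca1+ and subcutaneous ILCs. With only the 2 groups compared in the fit, which leaves fewer libraries to estimate the spread, the first 3 of these comparisons gave 618, 47 and 560 genes. A stricter filter and robust dispersions each gave 1 gene highest in dermal Sca1+ ILCs. Without epidermal replicate 1 and subcutaneous replicate 1 together, 114 genes were highest in epidermal and 1 in dermal Sca1+ ILCs. With an estimated correlation, camera called 0 lists, against 31 at an unadjusted p under 0.05 and 69 by fry. Where no construction is named, the cause was not tested.

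Title numbers do not pair these samples by the labels, and the deviations of libraries with the same number had correlations of -0.038 to 0.114. The highest was that of epidermal replicate 1 and subcutaneous replicate 1, which carry the numbers 17 and 20 in the deposited names. All other libraries carry numbers from 1 to 8, so no dermal library lies in that run. Run and layer are therefore partly mixed in comparisons with the dermal groups. What the runs mark is not given by the labels. With title number as a replicate block, 64 genes differed within the dermis, 203 between dermal Sca1+ and subcutaneous ILCs, 33, 3 and 70 were highest in epidermal, dermal CCR6+ and subcutaneous ILCs, and 56 were shared between the contrasts. Other totals stayed within 1.5 times, but the genes higher in epidermal than in dermal CCR6+ and dermal Sca1+ ILCs became 72 and 252. With a block by runs of file numbers every total stayed within 1.5 times, while the genes lower in dermal Sca1+ than in subcutaneous ILCs became 101. Of the 235 calls of named genes, the title number block ended 20 and the block by runs 12.

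Leaving out single libraries gave 732 to 1081, 35 to 155, 157 to 420, 1192 to 1865 and 435 to 1372 genes in the order above. The lowest came without dermal CCR6+ replicate 2 for 35 and 435, without dermal Sca1+ replicate 1 for 157 and without dermal Sca1+ replicate 2 for 1192. The other libraries whose omission moved these counts by over 1.5 times were dermal Sca1+ replicates 1 (43) and 2 (51) within the dermis, dermal Sca1+ replicate 2 (219) and subcutaneous replicates 1 to 3 (188, 218, 191) between dermal Sca1+ and subcutaneous ILCs, dermal Sca1+ replicate 1 (1199) between epidermal and dermal Sca1+ ILCs, and subcutaneous replicate 1 (769) between dermal CCR6+ and subcutaneous ILCs. Genes highest in epidermal ILCs numbered 22 (without dermal CCR6+ replicate 1) to 114 (without epidermal replicate 1), in dermal CCR6+ 0 (without dermal CCR6+ replicate 2) to 11, in dermal Sca1+ 0 to 1, and in subcutaneous 34 (without dermal Sca1+ replicate 1) to 142. The other such libraries were epidermal replicates 2 and 3 (29, 27), dermal CCR6+ replicate 2 (29) and dermal Sca1+ replicates 1 and 2 (42, 35) for the first, epidermal replicate 1 (11), dermal CCR6+ replicate 1 (3) and dermal Sca1+ replicates 1 and 2 (0, 2) for the next, epidermal replicate 1 and both dermal CCR6+ libraries (1 each) for dermal Sca1+, and dermal Sca1+ replicate 2 (61) and subcutaneous replicates 1 to 3 (61, 61, 67) for subcutaneous ILCs. Shared genes numbered 31 (without dermal CCR6+ replicate 2) to 112, with 39 and 40 without dermal Sca1+ replicates 1 and 2, and lists past the threshold 70 to 82. A lone dermal library was assumed to vary like the other groups. At these depths 3 counts corresponded to 0.166 to 0.258 CPM per library, and levels near or below that rest on few counts.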

Other observations

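The tests of mammary epithelial and further NK cell genes were set up before their results were seen, and the tests of scaling, detected genes, other-cell RNA, shared keratin reads, depth and other splits were chosen after the result was seen.

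Ramp3, Ramp1 and Vipr2, from the list of receptors of neuropeptides, hormones and lipid mediators, differed over the 4 groups. Ramp1 and Vipr2 were both lowest in dermal Sca1+ ILCs, where Ramp3 was highest. Ramp3 was at 4.74 ± 1.84 CPM in epidermal ILCs (SD, n = 3), 281 ± 0.219 in dermal CCR6+ ILCs (n = 2), 479 ± 34.0 in dermal Sca1+ ILCs (n = 2) and 222 ± 35.4 in subcutaneous ILCs (n = 3). Ramp1, which pairs with the same receptor, was at 496 ± 93.8, 391 ± 93.2, 136 ± 19.0 and 419 ± 157 CPM in that order. Vipr2 was at 37.7 ± 9.59 and 37.1 ± 20.4 CPM in the first 2 groups, had no count in dermal Sca1+ ILCs and was at 13.5 ± 6.02 CPM in subcutaneous ILCs. These genes were singled out after their values were seen. Melanocyte transcripts stood out in 1 library, dermal Sca1+ replicate 1, with Pmel at 62.3 and Dct at 39.0 CPM. The immediate early gene Jun was at 232 CPM in epidermal replicate 1 and 749.5 CPM in subcutaneous replicate 1. These values of 1 gene do not set the libraries apart. The summed level of the immediate early and heat shock list was the highest of the group in each (13980 and 29190 CPM).

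Of the genes called between epidermal and dermal CCR6+ ILCs, 841 of 1001 were lower in the epidermis. Scaling as the whole cause is argued against by the share of higher calls, which was at most 35.6% over RLE factors, DESeq2 and limma on TPM, and fewer detected genes by a share of 23.4% without dermal CCR6+ replicate 1, when the remaining dermal library detected 15013 genes against 16014 to 16443 in the epidermal ones. RNA of fibroblasts, endothelial cells, macrophages and mast cells, which a sort for ILCs is meant to leave out, in the dermal libraries could account for lower counts in the epidermal ones, and all 36 lower genes of those lists had a higher mean in subcutaneous than in dermal CCR6+ ILCs, with a median log2 ratio of 1.28. Of the 9 lower type 2 ILC genes, Klrg1 (7.39), Il5 (3.34), Pparg (2.93), Areg (1.5), Gata3 (0.46) and Calca (0.22) had a higher and Rora (-0.24), Ccr8 (-0.71) and Icos (-2.62) a lower subcutaneous mean, and the last 2 were called higher in dermal CCR6+ than in subcutaneous ILCs (edgeR adjusted p = 0.0388 and 0.000108), but Ccr8 lost its call in a fit of these 2 groups alone (0.0717) and when any 1 library other than epidermal replicate 1 or subcutaneous replicate 3 was left out (up to 0.26). Of all 805 lower genes outside the lists of these other cells, 58.3% had a higher subcutaneous mean (median log2 ratio 0.28), so for them such RNA and a difference between ILCs of both layers cannot be told apart, because the layers differ in both.

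Krt8, Krt18, Krt19 and the casein gene Csn3 were high in subcutaneous libraries alone. Reads of the 7 keratins of the keratinocyte list counted as Krt8 are argued against as the main source, since these summed to at most 10.6% of the Krt8 level. Krt7, Krt18 and Krt19, also higher in subcutaneous than in dermal CCR6+ libraries, were not in that sum. Sharing of reads with them was not tested. RNA of mammary epithelial cells, which lie in subcutaneous fat and which a sort for ILCs is meant to leave out, is a candidate source. Of the 15 genes of a separate list of 19 with at least 10 counts, 80.0% had all 3 subcutaneous libraries above the other 7, against 6.43% of all 19285 genes with as many counts (0.83% for a random order), with Prlr at 361, Epcam at 256, Cited1 at 74.5 and Lalba at 1.51 CPM. Muc1, Spint1 and Spint2 did not, nor did 4 milk protein genes, since Csn1s2a, Csn2 and Wap had no count in any library and Csn1s1 had 5, of which 2 were subcutaneous; epidermal cells also express Epcam, Spint1, Spint2 and Ehf, and other glandular epithelia in that layer and a difference in the ILCs were not tested.

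Among the subcutaneous libraries, NK cell and type 3 cytokine transcripts were high in replicate 2 alone, with Gzma at 199, Klrb1c at 107, Ncr1 at 63.6, Il22 at 80.2 and Il17f at 43.5 CPM, and Il17f was as high in dermal CCR6+ ILCs (40.9 ± 2.05 CPM, n = 2). Greater depth is argued against by its total, which was 0.99 of the larger of the other totals. NK cells or their RNA may contribute, since 100% of 11 further NK cell genes with at least 10 counts were at least 2 times higher in it than in either other subcutaneous library, with Klrc1 at 68.8 and Klri2 at 32.1 CPM. The rise was not confined to NK cell genes. In replicate 2 the summed level of T cell genes was also the highest of its group (1086 against 764.1 and 986.9 CPM). That of B cell genes was 434.7 against 228.9 and 278.0 CPM, and a contribution of other lymphocytes was not tested. NK cell receptor genes of the Klra and Klrc families resemble each other and may share reads, Il22 and Il17f are not NK cell genes, and type 1 ILCs express several of the same genes, so these cells were not distinguished, and whether the sort left NK cells out is not given in the sources used here.

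The comparison of epidermal with subcutaneous ILCs has 10 splits of its 6 libraries, 1 of which gave as many genes as the real one (itself), so that no share under 0.05 is possible. The real split gave 3268 genes and the highest of the others 0, and at an unadjusted p under 0.05 the numbers were 5442 and 164 to 851.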
